A study of Mus musculus with 8 samples.

How the data were processed

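Gene expression was measured in back skin epithelium of 8 mouse embryos at embryonic day 15.5, 4 Foxi3 null and 4 wild type, with 1 array per embryo. Per the labels' protocols, epithelium was separated from dermis with dispase, RNA was column-purified for each embryo, and RNA was labelled with an Affymetrix whole-transcript kit. The series description states that the embryos were littermates from 4 litters on a C57/Bl6 background, and does not tie an embryo or a replicate number to a litter. Groups and replicate numbers were taken from the sample titles. The values used are deposited log2 intensities that, per the submitters' processing notes, the authors obtained with RMA, a procedure that corrects background, normalises between arrays and summarises probes. The version of RMA, the probe annotation, the genome build and any filter are not given in the sources used here, so no coordinates are printed. The deposited values hold 26165 Ensembl genes, of which 25000 carry a symbol and 1165 do not. Of 24958 distinct symbols, 23034 were found among the reference names of assembly GRCm38.p6, which served for names and gene neighbourhood alone, and other symbols were kept as the file gave them. The deposited group means on the log2 scale differed from means of the sample values by at most 7.5e-09. A further 8 columns of array values could not be matched to a sample by name and were not used, so that the alternative planned on them was not run.

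Arrays give no read depth, and their number limits the precision. Detection calls were not used here, so that low values cannot be told from background. RMA compresses large differences and the differences of dim genes, and near-identical paralogs such as Hbb-b1 and Hbb-b2, Hspa1a, and the Sprr2 genes can share probe signal. Sample medians lay between 5.15 and 5.29 on the log2 scale, and no pair of samples had identical values.

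The groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, in a two-sided test of all 26165 genes with Benjamini-Hochberg adjustment, a threshold of adjusted p under 0.05, no fold limit and no covariate. Log2 fold changes are Foxi3 null minus wild type, with standard errors from the moderated fit. For single values an exact permutation test over the 70 arrangements was used, whose smallest two-sided p is 0.0286. The tests, 24 gene lists and the alternatives planned were fixed before the data were examined. The lists cover hair placode and germ epithelium, hair follicle stem cells, the Shh, Wnt, Eda and NF-kB, Bmp and Tgfb, Fgf and Notch pathways, hair shaft and inner root sheath, basal epidermis, suprabasal and cornified epidermis, periderm, Merkel cells and cell cycle. They also cover dermal fibroblasts, dermal condensate, melanoblasts, leukocytes, endothelium, erythroid cells, skeletal muscle, Schwann cells and nerve, dissociation stress, and embryo sex. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists, each gene being represented by its probe summary of highest mean.

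Genes were named by rule. These were Foxi3, up to 15 genes per direction of largest change among those that passed, filled to 8 per direction with the genes of lowest unadjusted p, and up to 4 members of each list with the lowest unadjusted p. Predicted gene models were left out of the fill, and 1 gene that the rule names is not reported here. Alternatives were quantile normalisation, median centring, genes above the median intensity, 1 probe summary per symbol, array weights, an intensity trend with robust moderation, a sex covariate, the replicate number as a block, a fold limit of 1.5, an adjusted p under 0.1, no variance moderation, and leaving out each sample in turn. A block with trend and robust moderation, a block at the looser threshold, and leaving out both samples numbered 4 were added after seeing the data. The steps were tested on simulated data with the residual spread of these arrays. Of simulated changes of 0.5, 1 and 2 on the log2 scale, 44.78%, 88.06% and 95.45% were recovered among 26165 genes, and 9 of 161 calls were false. Both shifted lists were called, as was 1 of 18 lists that shared no shifted gene. The simulated genes varied independently of each other and without litters. In the real data the estimated correlation was 0.45 within the suprabasal list and 0.69 within the stress list. The simulation therefore does not test camera's preset correlation, and its recovery rates need not carry over to data with fewer changed genes.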

Results

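To ask which transcripts depend on the forkhead transcription factor Foxi3 in embryonic skin, expression was compared between Foxi3 null and wild-type back skin epithelium at E15.5, in 4 embryos per group. At this stage the epithelium holds hair placodes and germs beside stratifying epidermis. Pearson correlations between samples across genes lay between 0.9877 and 0.9944 within groups and between 0.9845 and 0.9951 across groups. The mean log2 intensity of the embryo sex list was 6.23 in Foxi3 null 3, 6.28 in wild type 3 and 6.44 in wild type 4, and 3.74 to 4.02 in the other samples. That list averages Xist with Y-linked genes. Of the latter, Ddx3y was 7.69 in Foxi3 null 3, 7.98 in wild type 3 and 8.13 in wild type 4, against 2.34 to 2.67 elsewhere. By this gene the sexes were not balanced between the groups. The embryos came from 4 litters, and since no source ties an embryo to a litter, the comparison treats them as independent.

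Foxi3 (ENSMUSG00000055874), the targeted gene, had a mean log2 intensity of 8.42 ± 0.18 (SD, n = 4) in Foxi3 null and 8.95 ± 0.28 (SD, n = 4) in wild-type epithelium. The difference was −0.52 (SE 0.15), with 3 of 4 null samples below all wild-type samples. It did not pass over all genes (limma adjusted p = 1.00), and the exact two-sided permutation p was 0.057. Whether the probes lie inside the deleted part of the gene is not given in the sources used here, so the level neither bears out nor contradicts the genotype labels.

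Loss of Foxi3 was accompanied by lower Pthlh and Prss35 and higher Pgf transcript levels, and these 3 genes alone passed the test over all 26165 genes. Pthlh (ENSMUSG00000048776), which encodes parathyroid hormone-related protein, fell by 0.98 on the log2 scale (SE 0.08, limma adjusted p = 0.00733), from 7.12 ± 0.07 to 6.14 ± 0.12 (SD, n = 4 each). Prss35 (ENSMUSG00000033491), a serine protease family member, fell by 2.23 (SE 0.18, limma adjusted p = 0.00733), from 6.51 ± 0.34 to 4.28 ± 0.24. Pgf (ENSMUSG00000004791), a growth factor of the vascular endothelial growth factor family, rose by 0.88 (SE 0.07, limma adjusted p = 0.00733), from 4.80 ± 0.02 to 5.68 ± 0.13. For each, all 4 null samples lay beyond all wild-type samples. At unadjusted p under 0.05 limma gave 973 genes, against 1308 expected by chance alone. That count depended on the setting, with 707 genes without Foxi3 null 3, 1786 with array weights and 2194 without Foxi3 null 4. A count below 1308 thus does not show that no other gene differs. Among other settings, the 3 calls ended when wild type 1 (adjusted p = 0.0568), wild type 2 (0.0629) or wild type 4 (0.0537) was left out, and without variance moderation (0.119 for Pgf and Pthlh and 0.257 for Prss35), while without any 1 of these samples the log2 fold changes stayed between 0.87 and 0.89 for Pgf, −1.004 and −0.977 for Pthlh, and −2.20 and −2.17 for Prss35.

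Of the genes next in order, those given here did not pass, although in each all 4 null samples lay beyond all wild-type samples, which chance gives for a share of 0.0286 of genes. On the lower side stood the integrin subunit gene Itgb8 at −0.95 (SE 0.11, limma adjusted p = 0.0557). Lhx2, a LIM-homeodomain factor of hair follicle progenitors, was at −0.68 (SE 0.10), and the urea transporter gene Slc14a1 at −0.95 (SE 0.14), both with limma adjusted p = 0.268. The hyaluronan synthase gene Has3 was at −0.71 (0.282) and the adhesion molecule gene Ncam1 at −0.82 (0.428). On the higher side the Wnt inhibitor gene Dkk4 was at 0.92 (SE 0.17, limma adjusted p = 0.545) and Ctgf, which encodes a matricellular protein, at 0.86 (SE 0.16, 0.541). Fndc1 was at 0.60 and Pcdh20 at 0.47 (both 0.341), Aff2 at 0.51 (0.428), Mirlet7d at 0.67 (0.541), and the GDNF family receptor gene Gfra2 at 0.40 (0.544).

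**Figure D1:**
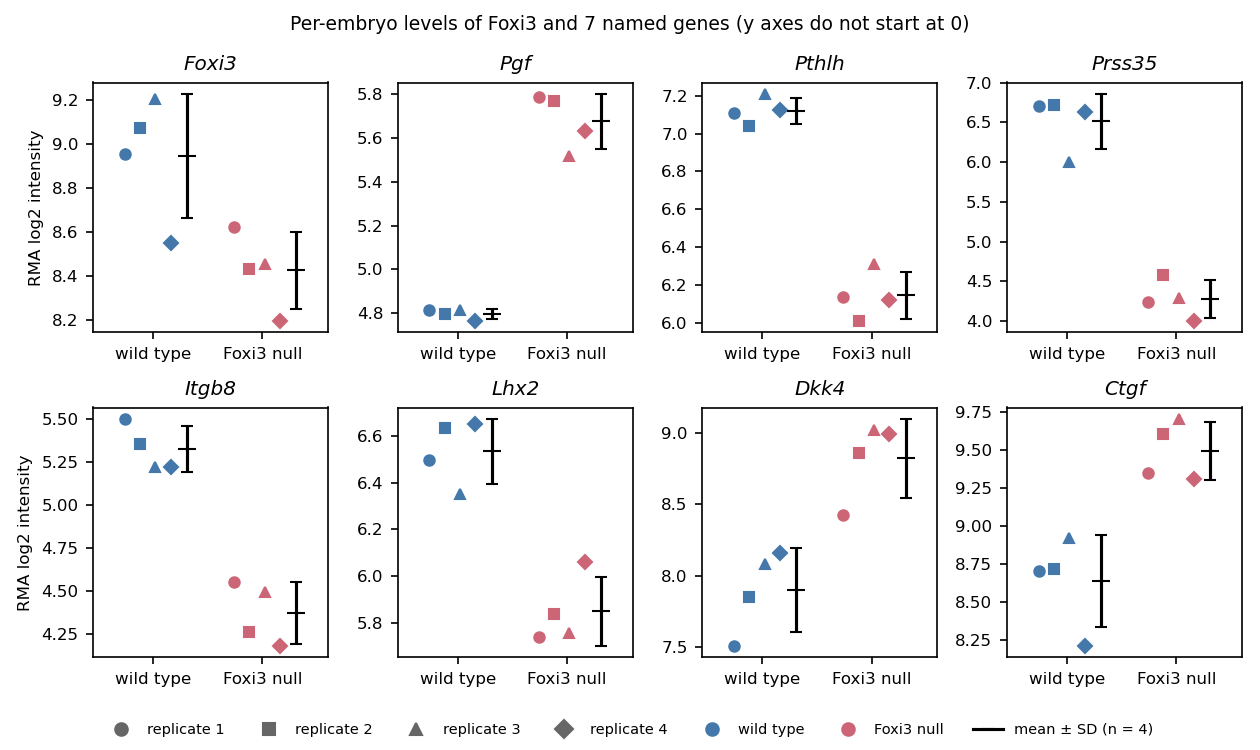
RMA log2 intensity (y axis) of Foxi3 and 7 other genes in each wild-type and Foxi3 null embryo, with symbols for the replicate number and bars for the mean ± SD of 4 embryos. The groups do not overlap for Pgf, Pthlh and Prss35, which passed the test, nor for Itgb8, Lhx2, Dkk4 and Ctgf, which did not, and Foxi3 in null 1 (8.62) lies above wild type 4 (8.55).

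The hair placode and germ genes held members that lay far apart in opposite directions. Of 24 measured members, 1 fell (Pthlh), 0 rose and 23 did not pass over all genes, while 2 were higher (Ctgf and Dkk4) and 2 lower (Pthlh and Lhx2) when adjusted over the list alone. Camera called no shared direction (adjusted p = 0.999), the mean being −0.01 and the test pointing up, but fry's test for change in either direction gave adjusted p = 7.75e-06, against 0.0868 or more for each other list. Few members can carry such a result, and Pthlh, which passed over all genes, is on no other list. In the same fry test, lists with Dkk4 (Wnt), Ctgf (Bmp and Tgfb) or Lhx2 (stem cell) had adjusted p = 0.354, 0.354 and 0.0963. The test was not repeated without Pthlh. Shh, the hedgehog ligand of placodes, was at −0.16 (exact permutation p = 0.0286, limma adjusted p = 1.00). Of 20 hair follicle stem cell genes 0 passed and 1, Lhx2, was lower when adjusted over the list alone. Nfatc1, a regulator of stem cell quiescence, was at −0.41 and Runx1 at −0.48, and camera gave adjusted p = 0.0714 for the list. That list was called lower without Foxi3 null 2 (adjusted p = 0.0201), after median centring (0.0191) and among genes above the median intensity (0.0483), but not with all samples at an estimated correlation (adjusted p = 0.530 with an estimated correlation).

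Among the signalling pathways no gene passed over all genes, and camera called the Wnt list alone. Of 38 measured Wnt genes 25 were above 0, with a median of 0.06, and camera's call (adjusted p = 0.0317) was lost with an estimated correlation (adjusted p = 0.530 with an estimated correlation). Its members pointed in different ways, since the inhibitor gene Dkk4, higher when adjusted over the list alone, stood beside Dkk3 at −0.28, the receptor gene Lgr5 at −0.21 and Kremen1, a receptor for Dkk proteins, at −0.14. The call also ended without Foxi3 null 2 (adjusted p = 0.157), Foxi3 null 3 (0.0834), wild type 2 (0.0740) or wild type 4 (0.0927), and after quantile normalisation (0.0581) or median centring (0.0712). Adjusted over the list alone, 1 of 28 Eda and NF-kB genes (Dkk4) and 1 of 30 Bmp and Tgfb genes (Ctgf) were higher, and 0 of 14 Shh, 22 Fgf and 18 Notch genes were called. For these lists camera gave adjusted p = 0.679 for Eda and NF-kB, 0.673 for Bmp and Tgfb, 0.533 for Shh, 0.977 for Fgf and 0.185 for Notch, and the Eda and NF-kB median (−0.01) opposed its mean (0.02).

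Genes of the suprabasal and cornified epidermis, the outer layers that form the barrier, were lower as a group in Foxi3 null epithelium. Of 43 measured members 41 lay below 0, with a median of −0.17, and camera gave adjusted p = 2.07e-07. The call was lost with an estimated correlation (adjusted p = 0.530 with an estimated correlation), and no member passed over all genes or adjusted over the list alone. The transglutaminase gene Tgm5 was at −0.47, filaggrin (Flg) at −0.21 and Sprr2d at −0.52, while Tgm3 was at 0.17. Flg and Sprr2d were dim (3.60 and 3.57 in wild type). Involucrin (Ivl) at −1.19 and Sprr3 at −1.28 were chosen after their values were seen, as were the keratin genes Krt1 at −0.06 and Krt10 at −0.03. The differences were thus uneven over the list, with quartiles of −0.39 and −0.08. The list mean was 7.90 ± 0.29 in null and 8.20 ± 0.31 in wild-type samples (SD, n = 4 each), an overlap with an exact two-sided permutation p of 0.229.

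Cell cycle genes were higher as a group, with 32 of 35 above 0 and a median of 0.13 (camera adjusted p = 2.55e-06; adjusted p = 0.530 with an estimated correlation). No member passed over all genes or adjusted over the list alone. The mitotic cyclin gene Ccnb1, dim at 3.65 in wild type, was at 0.22. Cenpf was at 0.32 and the proliferation marker Mki67 at 0.23, while the cell cycle inhibitor gene Cdkn1a was at −0.24. The list mean was 8.64 ± 0.09 in null and 8.53 ± 0.15 in wild-type samples (SD, n = 4 each, exact two-sided permutation p = 0.286), and wild type 3 (8.72) lay above 3 of the 4 null samples. The samples numbered 4, with the highest dissociation stress means (8.28 in null and 9.09 in wild type), had the lowest cell cycle mean (8.55 and 8.38) and the highest suprabasal mean (8.19 and 8.50) of their groups. Merkel cell genes were lower as a group, with 11 of 14 below 0 (camera adjusted p = 0.00891; adjusted p = 0.561 with an estimated correlation). Of the Merkel cell genes 0 passed over all genes, and Pou4f3, a transcription factor of these mechanosensory cells, at −0.51 was the 1 lower gene when adjusted over the list alone. Atoh1, which specifies these cells, was at −0.76 and the synaptic gene Snap25, dim at 3.26 in wild type, at −0.18. The Merkel list mean was 5.41 in Foxi3 null 4, above wild type 1, 3 and 4, against 5.14 to 5.15 in the other null samples, and the exact two-sided permutation p of the list mean was 0.114. Its members Krt8 and Krt18 are on the periderm list as well. In Foxi3 null 4 Krt8 was 9.77, against 8.62 to 9.02 in the other null samples, while Atoh1 was 5.05, against 4.75 to 5.07. The Merkel call ended without Foxi3 null 2 (adjusted p = 0.0836) or wild type 2 (0.0689).

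Basal epidermis, periderm, and hair shaft and inner root sheath genes gave no call, with 0 members passing over all genes or adjusted over the list alone. Camera gave adjusted p = 0.673 for 18 basal genes, 0.533 for 14 periderm genes and 0.185 for 29 hair shaft and sheath genes. Members of these lists included the keratin gene Krt79 at −1.18, the tight junction gene Cldn6 at 0.99 and Krt23 at −0.83. For Krt79 all 4 null samples lay below all wild-type samples (exact permutation p = 0.0286, limma adjusted p = 1.00), and it passed only without wild type 3, at −1.52 (adjusted p = 0.00441). The hair shaft and sheath list was called without wild type 1 (adjusted p = 0.0222), and with all samples it had adjusted p = 0.766 with an estimated correlation.

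**Figure D2:**
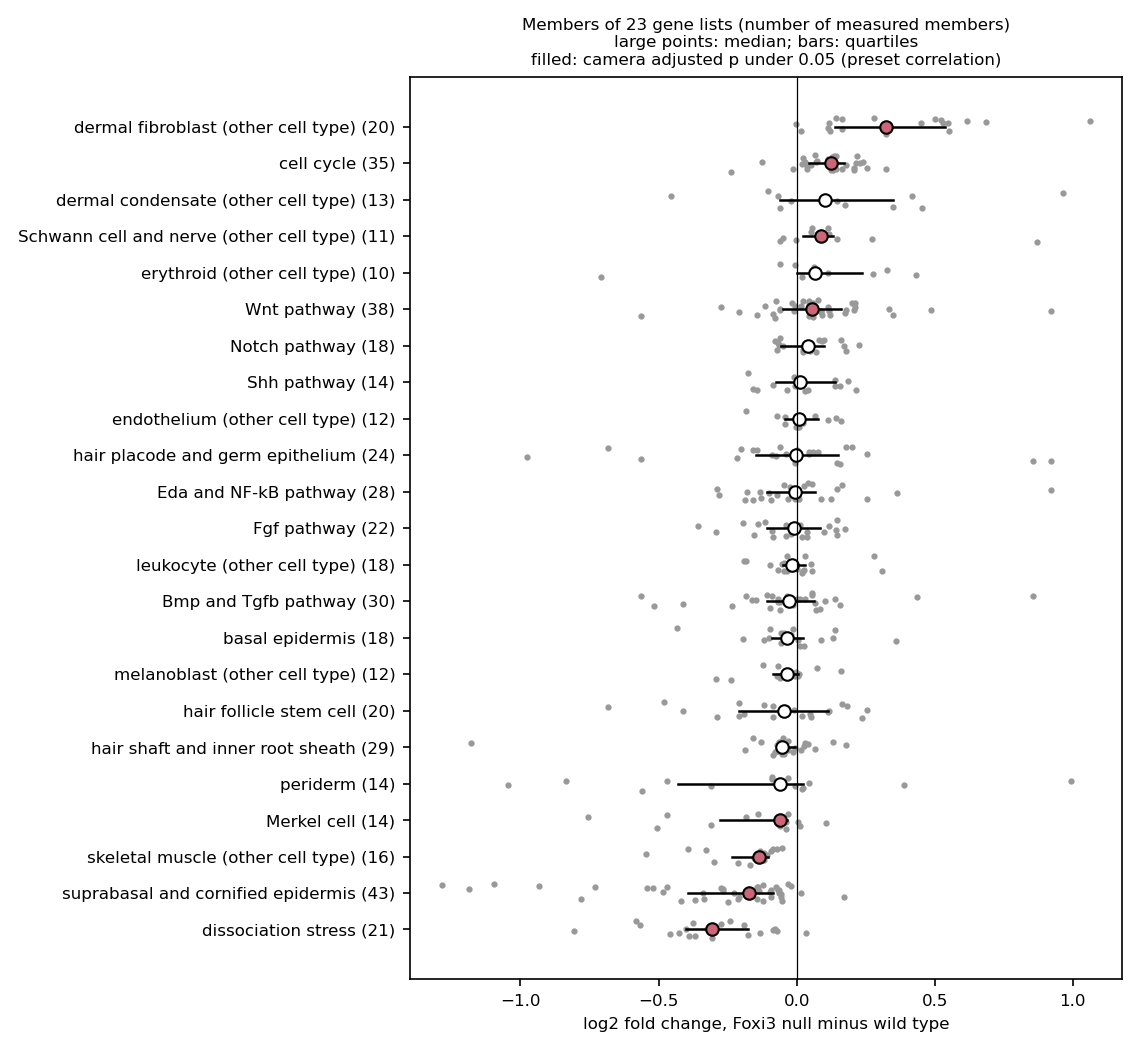
Log2 fold changes (x axis, Foxi3 null minus wild type) of the members of 23 gene lists (y axis, with the number measured), with the median as a large point, filled where camera called the list at the preset correlation, and bars for the quartiles. The embryo sex list is left out. Suprabasal genes have a median of −0.17 and cell cycle genes of 0.13, while the placode list centres on 0 with members near −1 and 1.

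Markers of other cell types and of handling also differed between samples. Dermal fibroblast genes were higher as a group, with 19 of 20 above 0 (camera adjusted p = 8.85e-06; adjusted p = 0.530 with an estimated correlation), but Foxi3 null 2 stood at a list mean of 7.97 against 6.40 to 6.68 elsewhere. Without that sample the difference of the list mean went from 0.362 to 0.00238 and the call ended (adjusted p = 0.810). The same sample had the highest mean of the dermal condensate (5.81), Schwann cell and nerve (6.25) and Wnt (8.01) lists. Schwann cell and nerve genes were called higher (adjusted p = 0.0496; adjusted p = 0.530 with an estimated correlation), a call that ended without Foxi3 null 1 (0.0879), Foxi3 null 2 (0.510), wild type 1 (0.149), wild type 2 (0.0674) or wild type 3 (0.202), with the sex covariate (0.132), after quantile normalisation (0.0581) or median centring (0.05004), and among genes above the median intensity (0.0734). Skeletal muscle genes were lower, with 16 of 16 below 0 and a median of −0.14 (camera adjusted p = 5.95e-07; adjusted p = 0.530 with an estimated correlation), among them Myl1 at −0.39 and Acta1 at −0.30. Their list mean was 5.19 in wild type 1 and 5.22 in wild type 2, while wild type 3 (4.90) and 4 (4.96) lay within the null range of 4.82 to 4.98. The exact two-sided permutation p of that mean was 0.0857. In wild-type epithelium 6 of the 16 muscle genes were above the median of all genes. Dissociation stress genes, immediate-early genes induced by handling, were lower (20 of 21 below 0, camera adjusted p = 0.0149; adjusted p = 0.766 with an estimated correlation). Their list mean was 8.28 in Foxi3 null 4 and 9.09 in wild type 4, against 7.30 to 7.58 elsewhere. This call ended without wild type 4 (adjusted p = 0.406), Foxi3 null 1 (0.0833) or Foxi3 null 2 (0.0805), and with the sex covariate (0.192). Leaving out wild type 4 alone keeps the high Foxi3 null 4 in the null group. The samples numbered 1, 2 and 3 had stress means of 7.30, 7.34 and 7.41 in null and 7.58, 7.39 and 7.52 in wild type. Dermal condensate (adjusted p = 0.0511), erythroid (0.136), melanoblast (0.673), endothelium (0.673), leukocyte (0.999) and embryo sex (0.533) genes gave no camera call, and apart from the Wnt list described above, in none of the lists of this paragraph did a member pass over all genes or adjusted over the list alone. The condensate list was called without Foxi3 null 1 (adjusted p = 0.0219), Foxi3 null 3 (0.00215) or wild type 2 (0.00946), the erythroid list without Foxi3 null 3 (0.0157) or wild type 2 (0.0481), and the sex list without Foxi3 null 3 (0.0271). With all samples these had adjusted p = 0.710, 0.530 and 0.766 with an estimated correlation.

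**Figure D3:**
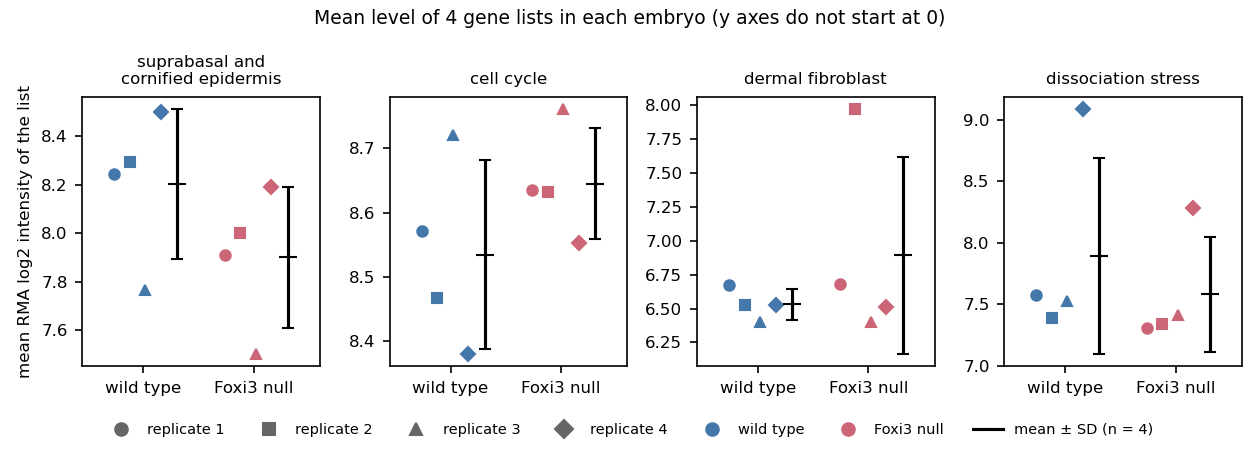
Mean RMA log2 intensity (y axis) of the suprabasal and cornified, cell cycle, dermal fibroblast and dissociation stress lists in each embryo, with symbols for the replicate number and bars for the mean ± SD of 4 embryos. Foxi3 null 2 stands at 7.97 for fibroblast genes, and both samples numbered 4 stand at 8.28 and 9.09 for stress genes.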

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

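The tests of the fibroblast and suprabasal patterns were chosen after the results were seen. A sample was singled out where its gap to the nearest other sample of its group was a large part of the group's range, which is the value given for each. This held for 26 of 254 values tested, against about 13 by chance. In Foxi3 null 3 the Y-linked genes stood high, with gap shares of 0.969 (Ddx3y), 0.984 (Eif2s3y), 0.977 (Uty) and 0.944 (Kdm5d), and 0.89 for the mean of the sex list. In the samples numbered 4 the stress list stood high, with 0.888 in wild type and 0.891 in null, as did Atf3 (0.863) and Socs3 (0.84) in wild type 4 and Btg2 (0.852) in null 4. Wild type 4 also stood high for the basal epidermis mean (0.96) and Fbn1 (0.856), and low for Rspo3 (0.934) and Hbb-b1 (0.856). Foxi3 null 4 stood high for the Merkel mean (0.951). Foxi3 null 2 stood high for Stmn2 (0.901), Rspo3 (0.906) and Tbx18 (0.866). Wild type 3 stood low for Prss35 (0.873) and Cav1 (0.951). Wild type 2 stood high for Dkk3 (0.843) and Pou4f3 (0.877), null 3 high for Hhat (0.867) and low for Pou4f3 (0.882), and null 1 high for Fndc1 (0.901) and Hbb-b1 (0.844).

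Dermal fibroblast genes were higher in the null group by a list mean of 0.362. A genotype effect in every null embryo is argued against, since only 2 of 4 null samples lay above all wild-type samples. Foxi3 null 2 alone carried the group difference, which was 0.00238 without it, within the wild-type SD of 0.112, but leaving it out does not show the source. Of the 6 most abundant members, Vim (11.20 against 10.58 to 10.81), Sparc (10.37 against 10.01 to 10.27), Dcn (11.45 against 11.30 to 11.44) and Col5a1 (7.08 against 6.79 to 7.06) stood above the other samples in null 2, while Postn (11.13) and Fn1 (8.59) lay within their range, and 14 of the 20 genes were above the median of all genes in wild-type epithelium. Null 2 also had the highest list mean of condensate genes (5.81 against 5.02 to 5.27). The same held for Schwann cell and nerve genes (6.25 against 5.72 to 5.84). Erythroid (4.61 against at most 4.54) and leukocyte genes (4.584 against at most 4.577) stood barely above. Endothelium (4.54), melanoblast (6.39) and skeletal muscle genes (4.98) lay within the range of the other samples. Not every marker list thus singled out null 2. In wild-type epithelium, however, 2 of 12 endothelium and 2 of 18 leukocyte genes were above the median of all genes, so those lists can show little. Dermal RNA carried over in that sample and a change in that embryo's own cells both stay open.

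Suprabasal and cornified genes were lower in the null group by a list mean of −0.30. Dilution by dermal RNA in Foxi3 null 2 is argued against, since the difference was −0.33 without it, and so is stress of the samples numbered 4, since it was −0.30 without both. Genotype and a lower epidermal maturity of the null embryos stay open and cannot be told apart, since maturity was not measured apart from these genes; the null sample was lower in all 4 same-numbered comparisons, which counts only if the numbers mark litters. Chance placement of embryos that vary in maturity stays open, since the exact permutation test (p = 0.229) ignores litters and the labels do not tie the numbers to them.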

How the results depend on the processing

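The number of genes higher and lower (1 and 2) was unchanged under quantile normalisation, median centring, genes above the median, 1 summary per symbol, array weights, trend and robust moderation, the sex covariate and a fold limit of 1.5, and was 1 and 3 at an adjusted p under 0.1. It was 0 and 0 without moderation (868 genes at unadjusted p under 0.05) and with both samples numbered 4 left out, which was chosen after seeing the data and gives fewer samples. Leaving out each sample in turn gave 0 to 1 higher and 0 to 3 lower genes. With the replicate block the counts were 0 and 0 (limma adjusted p = 0.0517 for Pthlh and Prss35 and 0.0726 for Pgf). The block gave 2339 genes at unadjusted p under 0.05, against 1308 expected by chance. Of the 8 lists, the Schwann cell and nerve list lost its call with the block (camera adjusted p = 0.0799). The block at an adjusted p under 0.1 gave 5 and 28, and the block with trend and robust moderation 10 and 61, among them the 3 genes. Both were chosen after seeing the data and after the plain block had given 0. The latter was picked because its order lay closest to that of the deposited gene list (Spearman 0.9967, against 0.9825 for no block), among more fits than the 4 whose values were kept, and its counts are therefore no independent evidence. Deviations of same-numbered samples correlated at 0.13, −0.04, 0.49 and 0.36, and not every sample correlated best with its own number, so the numbers were not taken to pair samples. That choice does not exclude pairing, since the same-number matching was the closest of 24 for the suprabasal list. The Foxi3 difference kept its sign in all alternatives, −0.65 to −0.44 with a sample left out. Lists called numbered 8, but 0 with an estimated correlation or with fry's test of 1 shared direction, and 4 (without Foxi3 null 2) to 10 with a sample left out. The sex covariate was the mean of Kdm5d, Ddx3y, Eif2s3y and Uty themselves. It turned Uty (0.10) and Kdm5d (0.12), whose small differences under it were therefore fixed in advance. Leaving out both samples numbered 4, where Uty was 1.935 in null and 6.969 in wild type, also turned both (Uty 0.051, Kdm5d 0.012). With a sample left out, Uty ranged from −2.48 to −0.35, Kdm5d from −1.96 to −0.24, Mrc1 from −0.0024 to 0.42, Stmn2 from −0.036 to 1.25, and Btg2 from −0.58 to 0.0081. The stress list's camera adjusted p ranged from 0.000176 to 0.406. Its direction turned without wild type 4, a setting that keeps the high Foxi3 null 4. Apart from the Y-linked genes, the causes of these changes were not tested. Single named genes kept direction and side of the threshold in 1868 comparisons of settings, lost a call in 18, gained one in 7 and turned in 7. All 18 losses were of Pgf, Pthlh and Prss35, the only genes that had a call to lose. Most of the 1868 comparisons were thus of genes that stayed without a call, and they do not show that the 3 calls are stable. Signal over background was not given, so that dim genes such as Hbb-b2 (2.01 in wild type) cannot be told from background. The same holds for Ccnb1, Flg, Sprr2d and Snap25 (3.65, 3.60, 3.57 and 3.26 in wild type).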

Other observations

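The tests of maturity and of replicate numbers were chosen after the results were seen, and the counts of other splits were planned. Around Foxi3, the 40 nearest measured genes of chromosome 6, 20 per side, gave 0 that passed, 2 at unadjusted p under 0.05, and log2 fold changes from −0.62 to 0.37. Periderm genes went apart, with Cldn6 at 0.99 and Gabrp at 0.39 beside Krt23 at −0.83, Krt6b at −0.56 and Krt8 at −0.47, none of which passed. Among hemoglobin genes, Hbb-b2 was at 0.43, Hbb-b1 at 0.33, Hbb-y at 0.28, Hba-x at 0.07 and Hbb-bh1 at −0.06 (the last pair chosen after their values were seen), while Slc25a37, a mitochondrial iron transporter gene, was at −0.71. None of these passed.

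Chance is not excluded for either count by splits of the samples, which ignore litters. Of the 35 splits of the 8 samples, 2 gave as many genes, the real split giving 3 and the highest other 324, and 10 gave as many lists, the real split giving 8 and the highest other 11. The split with 324 genes set Foxi3 null 1, 2 and 3 and wild type 3 against the other 4 samples, which points to a structure of the samples that crosses genotype. These 4 samples were also the 4 with the lowest suprabasal list means.

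A hypothesis is that the replicate number marks a litter. The null minus wild-type differences of the suprabasal list between same-numbered samples were −0.335, −0.292, −0.266 and −0.308 (mean −0.30, SD 0.029, n = 4). Of the 24 ways to match null with wild-type samples, 1 had a spread as small, the same-number matching itself, and the median spread over all matchings was 0.436. This is consistent with shared litters or shared preparation, which the test does not separate. The same-number matching was also the 1 closest for the Bmp and Tgfb, periderm, cell cycle and dermal condensate lists. For the other lists, from 2 of 24 matchings (hair follicle stem cell and melanoblast) to 15 of 24 (Notch) had a spread as small, with 12 of 24 for placode genes. The same-number spread lay below the median of all matchings for every list but Notch (0.0546 against 0.0521).

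A further hypothesis is that a lower epidermal maturity of null embryos, rather than genotype, could underlie the changes of Pgf, Pthlh and Prss35. With the suprabasal list mean as a covariate, the smallest part of a log2 fold change kept was 94.3% (Prss35, −2.11 with SE 0.20, from −2.23 with SE 0.18). The list mean differed by −0.30 between groups, about its SD within them (0.29 and 0.31). The SDs within groups were at most 0.13 for Pgf and 0.12 for Pthlh, and 0.24 and 0.34 for Prss35. All were small beside the changes of these 3 genes. The covariate could thus remove little of their changes. The result shows only that a linear relation to this list mean did not carry them, and it does not decide on maturity. Pthlh stayed past the threshold (adjusted p = 0.0182), and Pgf and Prss35 did not (both 0.052), with standard errors of 0.08 for Pgf and 0.20 for Prss35 against 0.07 and 0.18 without the covariate.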
